A study of Mus musculus with 20 samples.

How the data were processed

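ATAC-seq, chromatin-associated RNA sequencing (ChrRNA-seq) and m6A sequencing of chromatin-associated RNA (Chrm6A-seq) were analysed from mouse embryonic stem cells (ESCs) and from cardiomyocyte cultures (CM) derived from them through embryoid bodies, each wild type (WT) or knockout (KO) for Mettl3, which encodes the catalytic subunit of the nuclear m6A methyltransferase. Groups were taken from the sample titles. ATAC-seq had 3 libraries in each of the 4 groups, 12 in all. ChrRNA-seq and Chrm6A-seq had 1 sample per group. The labels of CM KO replicate 3 of ATAC-seq name RNA as the molecule, while its file has the layout of the other peak lists, and it was used as ATAC-seq. Nothing in the labels says whether libraries of a group came from separate cultures, so the ATAC-seq p-values measure only the spread between these libraries, which may be technical.

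The submitters' processing notes name cutadapt, Bowtie, Picard, MACS2 and HISAT2 and the genome build mm10. They give no role, order, version or parameters, and the rest of the processing is not given in the sources used here. Per the labels' protocols, ATAC-seq was sequenced single end. Whether reads were shifted for the transposase offset is not stated.

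Each ATAC-seq library had its own deposited peak list in the narrowPeak layout of MACS2, so peaks were called per library. The deposited columns are a score, the fold enrichment of the summit over the local background of the same library (a ratio), and the −log10 p-value and −log10 q-value of the summit. These are the authors' values and were used only within a list. The lowest −log10 q in every list was close to 1.30. Several summits of one interval were counted as 1 interval. No list states its read depth. Under the Poisson model of MACS2, the fold and the p-value of a summit together fix a background pileup, which was solved for each library and used as its relative depth. Total reads and the share of reads in peaks are not given in the sources used here, so thinning matched this pileup only. It ranged from 1.58 to 2.53 reads per base. The largest misfit of this solution was 0.000127. Union regions were made by merging the intervals of all 12 libraries that shared at least 1 bp, which gave 193427 regions. A region was called opened in a comparison when it was called in 3 of 3 libraries of the first group and 0 of 3 of the second, and closed in the reverse case. With 3 libraries against 3, Fisher's exact test and the two-sided exact permutation test cannot go below p = 0.1, so these tests cannot pass 0.05 for a pair of groups. The difference of the KO effect between cell types was tested on log2 interval numbers by permuting the genotype labels within each cell type, two-sided, over 400 arrangements with a smallest p of 0.005. So that no WT CM library was scored on regions it helped to choose, regions opened or closed in WT differentiation were defined without 1 WT CM library at a time. They were then scored in that library and in the KO libraries. The regions were still chosen by WT libraries, so the contrast with KO is not free of that choice.

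The planned test of promoters could not be run as written, because the gene table used here (RefSeq genes of GRCm38.p6, the assembly behind mm10) gives no strand. A gene end was used in its place, defined as either end of the gene plus or minus 1 kb, over 21900 protein-coding genes. An interval at a gene end can therefore lie at the start or at the end of the gene. Of 471 members of the gene lists, 459 were found in the gene table.

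The deposited ChrRNA-seq files hold 1 value per gene and condition with Ensembl gene identifiers and no header. The authors named the values RPKM, that is, reads scaled to gene length and to all mapped reads. The annotation, the strandedness and the number of cultures behind each file are not given in the sources used here. RPKM values are not counts, and no count test was run. Between 99.5% and 99.6% of identifiers matched a gene symbol. A gene not listed in a file was taken as 0 in the counts of genes, but absence from a list can also come from reads assigned to an overlapping gene, so no fold is given against it. Depth was estimated from the spacing of low RPKM values, which gave about 28000000, 28100000, 29400000 and 29800000 reads for the ESC WT, ESC KO, CM WT and CM KO libraries. Between 54.0% and 55.9% of genes with 1 to 10 estimated reads lay within 0.05 of a whole number. The gene lengths behind the RPKM values were thus matched for only part of the genes, and the estimated reads are approximate. Log2 ratios were computed on RPKM + 1, which understates the change of low genes. Folds are ratios of RPKM with 95% Clopper-Pearson intervals on estimated reads. They cover counting error only and compare 2 libraries, not 2 conditions. Genes at least 2-fold higher or lower were counted among genes with at least 1 RPKM in either library. The median log2 ratio of a gene list was set against 10000 random lists of the same size matched on mean expression in 20 bins. Its percentile describes these libraries and is not a test. Values of a gene that overlaps another are uncertain, since the reads of both cannot be told apart without strand.

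The deposited Chrm6A-seq files list a gene, a position within the gene and a 4-base motif, with no score, width or read count. Whether a position counts from the gene start on the genome or along the transcript is not stated, so positions were compared only within the same gene and were not placed on the genome. Repeated lines were removed. Shares of positions have 95% Clopper-Pearson intervals that cover counting error only. Read depth of these libraries is unknown, and the number of positions depends on it.

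Named genes followed a rule fixed before the data were examined. It took the 10 protein-coding genes with the highest and the 10 with the lowest log2 ratio among genes with at least 5 RPKM in the higher library (predicted genes left out), the list members with the largest ratios and at least 1 RPKM, list members whose gene end was called in 3 libraries of one group and 0 of the other, and for m6A the list members with positions in WT and not in KO, ranked by expression, with the 5 highest expressed genes that kept a position. The gene lists, fixed at the same time, cover pluripotency, cardiac transcription factors, sarcomere, calcium and conduction, cardiac energy metabolism, early mesoderm, smooth muscle, fibroblast, endothelial, blood, neural, endoderm, skeletal muscle, genes of the 2-cell stage, the m6A machinery, chromatin regulators, chromatin-associated long noncoding RNAs, cell cycle, p53 targets, interferon response, WNT and BMP signalling, immediate early genes, ribosomal proteins and mitochondrial transcripts. Genes named outside the rule are said to be so, and some genes that the rule takes are not reported here.

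The analysis used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The code of each step was checked on simulated data. With the groups CM WT and ESC WT, 100% of 200 regions planted in each direction among 193427 were recovered. In CM WT values of 22332 genes, 200 genes of at least 5 RPKM were changed 4-fold in each direction without noise, and 100% were recovered. The planted regions met the calling rule exactly. Both checks were thus bound to succeed and do not measure recovery in real libraries. The alternatives were a −log10 q of at least 5, autosomes and X only, an equal number of intervals per library, 50% cover of the union region, calls in 2 of 3 libraries, other gene end widths, the replicate number as a block, each library left out in turn, a pseudocount of 0.1, other RPKM filters, scaling to a median log2 ratio of 0, and expressed genes only for m6A. Alternatives chosen after seeing the data were the thinning of all 12 ATAC-seq libraries to the lowest background pileup, the gene body plus 2 kb, m6A positions within 100 bases, only genes listed in both ChrRNA-seq files, and the KO effect between cell types with each library left out. Enrichment of the motif over flanking sequence was not analysed here, because no genome sequence was used.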

Results

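Chromatin accessibility, chromatin-associated RNA and its m6A were measured in mouse ESCs and in cardiomyocyte cultures derived from them, with or without METTL3. ATAC-seq marks open chromatin by the insertion of a transposase. ChrRNA-seq measures RNA held on chromatin, which is rich in nascent transcripts, and m6A is the methylated adenosine that METTL3 writes on RNA. Each ATAC-seq group had 3 libraries with between 70132 and 119307 called intervals. The 1 ChrRNA-seq library of each group listed 18428 genes in ESC WT, 18557 in ESC KO, 19732 in CM WT and 19733 in CM KO, at about 28000000, 28100000, 29400000 and 29800000 estimated reads. The ChrRNA-seq and Chrm6A-seq groups had no replicates, so their differences have no replicate check and no p-value.

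Mettl3 itself, at chromosome 14 positions 52294841 to 52308741 of mm10, stood at 1.73 RPKM in ESC WT, 1.28 in ESC KO, 1.18 in CM WT and 1.07 in CM KO. Its ratio of KO to WT in ESCs was 0.742 (0.660 to 0.835), and the gene overlaps Tox4. The deleted part of the gene is not given in the sources used here, and chromatin RNA counted over a whole gene does not show whether the protein was made. The level of Mettl3 therefore does not check the labels, and KO and WT stand throughout for libraries labelled KO and WT.

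The first comparison asked what changed on differentiation in WT cells. Pluripotency genes were lower and cardiac transcription factor, sarcomere, fibroblast and endoderm genes were higher in chromatin RNA of CM WT than of ESC WT. Tdgf1, a NODAL co-receptor, stood at 3.41 against 30.2 RPKM (fold 0.113, 0.104 to 0.123), and Zfp42 (Rex1) at 0.837 against 9.20 RPKM. Of 28 pluripotency genes in the filter, 26 had a negative log2 ratio and 20 were at least 2-fold lower, with a list median of -1.34 that lay below every matched random list (percentile 0). The 9 cardiac transcription factors in the filter were all higher, with a median of 1.16 at percentile 100. Fewer than 3 members of this list reached 1 RPKM in ESC WT, as for the sarcomere, fibroblast and endoderm lists. Most genes of these lists thus passed the filter through CM WT alone, which fixed their direction. Gata4, a cardiac regulator, stood at 2.01 against 0.0270 RPKM, and Tbx20 at 2.01 against 0.0314 RPKM. The 6 sarcomere genes were also all higher, with a median of 1.08 at percentile 99.97 (0.20 at percentile 99.99 over all 24 listed members), among them cardiac actin Actc1 at 1.90 against 0.0114 RPKM and alpha myosin heavy chain Myh6 at 1.27 against 0.00430 RPKM. Myh6 overlaps Cmtm5, and its ESC value rests on very few reads.

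Genes of other lineages were higher in the same CM WT library. The fibroblast list had a median of 2.22 at percentile 100 over 7 genes, with the collagens Col1a1 at 15.5 against 0.149 RPKM (104-fold, 82.3 to 134) and Col3a1 at 3.89 against 0.0112 RPKM. The endoderm list had a median of 1.55 at percentile 100 over 6 genes, led by the lipoprotein gene Apob at 10.3 against 0.0383 RPKM. Without the filter on low values the medians were 0.53 for fibroblast, 0.46 for endoderm and 0.51 for cardiac transcription factors, all at percentile 100. The embryonic globin Hbb-y stood at 18.2 against 0.0717 RPKM, and the blood list had too few members in the filter for a median. The WNT and BMP list (median 0.78, percentile 100) and the immediate early list (median 0.43, percentile 99.88) were high, and so were the chromatin-associated long noncoding RNAs (median 0.34, percentile 99.6), with Airn, which overlaps Igf2r, at 7.46 against 0.286 RPKM. Cell cycle genes were lower, with a negative ratio in 25 of 25 genes and a median of -0.58 at percentile 0.25, and the 3 neural genes in the filter went both ways (median -1.85, percentile 0.015), with Stmn2 at 0.485 against 4.36 RPKM and Nes at 1.28 against 0.366 RPKM (3.51-fold, 2.78 to 4.43). Of chromatin regulators, Tet1, which overlaps another gene, and Tet2 oxidise 5-methylcytosine and stood at 1.45 against 11.8 and 0.944 against 5.42 RPKM, while the list median of -0.23 was at percentile 63.1. The ribosomal protein list (median -0.73, percentile 3.54), the p53 targets (-0.08, 91.4), cardiac energy metabolism (-0.17, 66.8), calcium and conduction (-0.19, 62.7) and the m6A machinery (-0.24, 56.2) lay within the middle 95% of random lists, and with scaled libraries the medians of chromatin regulators, p53 targets, energy metabolism and calcium genes turned positive.

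Among single protein-coding genes, the highest ratios of CM WT to ESC WT belonged to the growth factor Igf2 (32.4 against 0.392 RPKM, 82.8-fold), Hbb-y, Col1a1, Hbb-bh1, Hba-x, Apob, Adnp, Dlk1, Serpinh1 and Peg10. The lowest belonged to Tdgf1, Zfp42, Dppa5a, Fgf4, Tet1, Gdf3, Zfp981, Zfp57, Slc7a3 and Adam23. Adnp was listed only in CM WT, at 7.11 RPKM, and the overlapping Gm20716 held 4.82, 4.36, 0.651 and 5.25 RPKM in ESC WT, ESC KO, CM WT and CM KO, so its value depends on how reads were assigned. Igf2, Tet1, Zfp981, Slc7a3 and Adam23 also overlap other genes. In all, 270 genes were at least 2-fold higher and 381 at least 2-fold lower among 5865. The median ratio of all genes was shifted by -0.34, and with libraries scaled to remove this shift the counts were 459 higher and 249 lower, so the balance of higher and lower genes depends on scaling.

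ATAC-seq of the same comparison showed fewer called intervals in CM. CM WT libraries had 88791 ± 5064 intervals (SD, n = 3) and ESC WT libraries 112503 ± 6215, with no overlap between groups (exact permutation p = 0.1, the smallest possible). Regions opened numbered 11278 and regions closed 22155, at 193427 regions in all. With an equal number of intervals taken from each library the split was 10628 opened and 10244 closed, without an excess of closed regions. Equal numbers move such a split toward balance by construction. After thinning to the same background pileup the split was 9655 opened and 23669 closed. The gene end was opened at 169 genes and closed at 331. Opened gene ends from the lists included Gata4, Actc1, Lmod2 of the thin filament, the calcium channel gene Cacna1c, the mitochondrial creatine kinase gene Ckmt2, Acta2, Col3a1, Postn, Csf1r and Ifit1. Closed ones included the pluripotency gene Dppa3, Ldb3, Cox6a2, Icam2, Elavl3 and Pramel11. The ends of the noncoding H19 and Mir17hg, outside these counts of protein-coding genes, closed as well. The number of regions opened minus closed in or next to the genes of a list was ranked among random gene lists, so a percentile can come from either side. It was high for fibroblast genes (18 opened, 4 closed, percentile 100), endoderm genes (12 and 5, percentile 99.91), blood genes (11 and 4, percentile 99.7), smooth muscle genes (12 and 7, percentile 98.8) and cardiac transcription factors (24 and 21, percentile 98.7). It was low for chromatin regulators (8 opened, 51 closed, percentile 1.05) and cell cycle genes (0 and 13, percentile 2.46). Of 133 protein-coding genes in the chromatin RNA table whose end opened, 22 had at least 1 RPKM in either library and a median log2 ratio of 0.75 at percentile 100. Of 200 whose end closed, 19 did, with a median of -0.36 at percentile 18.1.

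**Figure D1:**
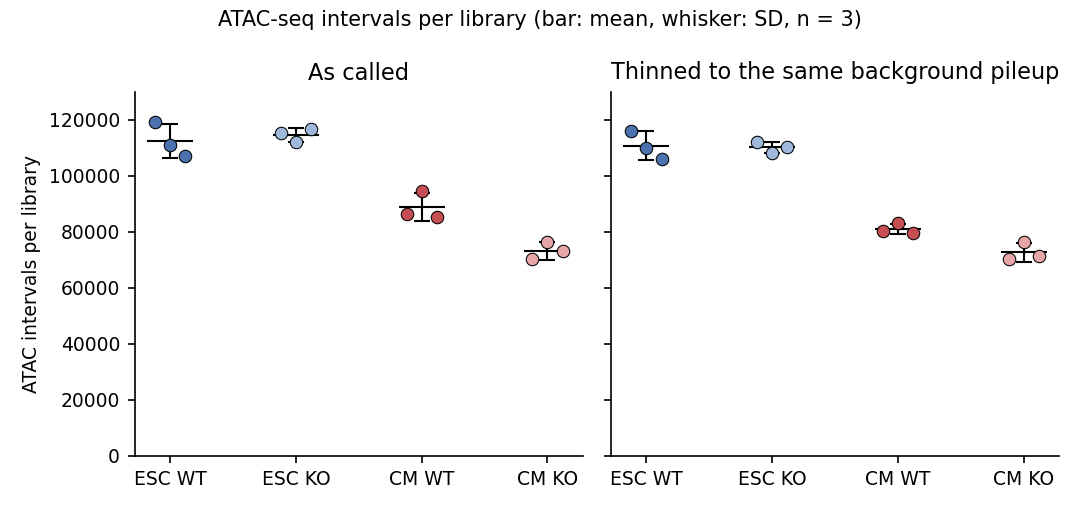
Number of ATAC-seq intervals per library for the 4 groups, as called (left) and after thinning of all libraries to the same background pileup (right). Points are libraries, the bar is the mean and the whisker the SD of 3 libraries; the CM KO libraries lie below all CM WT libraries in both panels.

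The second comparison asked what changed on differentiation in KO cells. Pluripotency genes were lower here too, with a negative ratio in 27 of 30 genes, 18 of them at least 2-fold lower, and a median of -1.18 at percentile 0. Zfp42 stood at 2.02 against 11.2 RPKM and Nanog at 1.76 against 7.17 RPKM. The 6 cardiac transcription factors in the filter were all higher (median 1.10, percentile 100), with Tbx20 at 1.78 against 0.020 RPKM, Gata6 at 1.64 against 0.0226 RPKM and Hand1 at 1.62 against 0.0433 RPKM. Tbx20, Gata6 and Hand1 passed the filter through CM KO alone, which fixed their direction. In CM WT against ESC WT 9 members passed, so the medians of the 2 comparisons are not over the same genes. Gata6 and Hand1 overlap noncoding genes. Only 2 sarcomere genes reached 1 RPKM in either KO library, Tpm1 at 5.96 against 1.94 RPKM and Pdlim5 at 1.00 against 0.827 RPKM. The fibroblast (median 1.17, percentile 99.97), WNT and BMP (0.87, 100), chromatin-associated long noncoding RNA (0.35, 99.51), immediate early (0.42, 99.03) and p53 target lists (0.28, 98.5) were high. The p53 targets included Plk2 at 3.67 against 0.969 RPKM and Cdkn1a, which encodes the cell cycle inhibitor p21, at 1.85 against 0.800 RPKM. Cell cycle genes were lower (median -0.23, percentile 1.67), and the chromatin regulators (-0.08, 36.3), the m6A machinery (0.02, 74.8), cardiac energy metabolism (0.05, 73.6), calcium and conduction (-0.16, 42.3) and ribosomal proteins (-0.48, 5.50) lay within the middle 95%.

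The highest single genes were Hbb-bh1 (28.0 against 0.0466 RPKM), Igf2, Peg10 (59.0 against 3.86 RPKM, 15.3-fold, 14.5 to 16.1), Hba-x, Amot, Hbb-y, Cd24a, Mest, Car4 and Peg3, and the lowest Spp1, Zfp42, Tdgf1, Fgf4, Tet1, Triml1, L1td1, Slc7a3, Dppa5a and Nanog. Of these, Igf2, Mest, Peg3, Tet1, Triml1 and Slc7a3 overlap other genes. At least 2-fold higher were 278 genes and at least 2-fold lower 204, among 5558, with a median shift of -0.11. Of the 270 genes higher in WT differentiation, 133 were also higher in KO differentiation (11.98 expected of independent lists), and of the 381 lower, 118 were also lower (12.4 expected).

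In KO differentiation more regions closed than opened. CM KO libraries had 73177 ± 3128 intervals (SD, n = 3) against 114635 ± 2404 in ESC KO, with no overlap (exact permutation p = 0.1). Regions closed numbered 18844 and regions opened 1833, a share opened of 8.86% of those that changed, against 33.7% in WT. With an equal number of intervals per library, which moves the split toward balance by construction, the counts were 5102 closed and 3851 opened, a share opened of 43.0% against 50.9% in WT. After thinning to the same background pileup 17115 regions closed and 1915 opened, a share opened of 10.1% against 29.0% in WT. The gene end opened at 22 genes, among them Acta2 and Tie1 of the lists, and closed at 320, among them Otx2, Ldb3, Gja5, Prrx1, Cubn, Ttr, Pramel11, Oasl1 and Egr2. Of 197 protein-coding genes in the chromatin RNA table whose end closed, 15 had at least 1 RPKM in either library and a median log2 ratio of -0.01 at percentile 42.4. The number opened minus closed was low among random lists for endoderm genes (1 opened, 17 closed, percentile 1.37) and high for cardiac transcription factors (7 and 16, percentile 98.6). Regions that opened in both genotypes numbered 1408 (107 expected of independent lists), and regions that closed in both 8319 (2158 expected).

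The third comparison was KO against WT in ESCs. None of the 11 gene lists with at least 3 members in the filter left the middle 95% of random lists in chromatin RNA, and the other lists, among them sarcomere, cardiac transcription factors, fibroblast and endoderm, had too few members for a median. The pluripotency median was -0.15 (percentile 12.4) with 13 of 29 genes positive, and its members went both ways. Lefty2 and Lefty1, antagonists of NODAL, were higher at 4.98 against 0.882 RPKM (5.64-fold, 4.74 to 6.78) and 3.46 against 0.836 RPKM (4.13-fold, 3.22 to 5.35). Lefty1 overlaps Gm39715. Dnmt3b, a de novo DNA methyltransferase, was lower at 0.911 against 2.07 RPKM (fold 0.440, 0.408 to 0.475), and Utf1 at 2.74 against 5.08 RPKM. Among chromatin-associated long noncoding RNAs (list median 0.08, percentile 86.3), Neat1 stood at 8.88 against 4.32 RPKM and Kcnq1ot1, which overlaps Kcnq1, at 8.43 against 3.84 RPKM, while Meg3, which overlaps Rtl1, stood at 3.34 against 6.45 RPKM. The other lists had medians of -0.05 for chromatin regulators (percentile 75.9), -0.10 for the m6A machinery (44.8), -0.14 for cell cycle (14.9), -0.14 for p53 targets (27.4), -0.23 for immediate early genes (10.7), 0.04 for WNT and BMP genes (91.5), 0.01 for cardiac energy metabolism (91.4), -0.22 for calcium and conduction (23.6) and -0.0038 for ribosomal proteins (38.4). With scaled libraries the medians of chromatin regulators and ribosomal proteins turned to 0.03 and 0.10.

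Among the 10 single genes with the highest ratios of ESC KO to ESC WT were Grcc10 (146 against 61.6 RPKM, 2.37-fold), the autophagy kinase gene Ulk1 (5.95 against 2.48 RPKM), Kpna1, Rps20, Trh, Mki67, Rpl23 and Camk1d, and those with the lowest Ifitm3 (4.69 against 10.7 RPKM, fold 0.438, 0.359 to 0.531), the gap junction gene Gja1 (3.04 against 6.87 RPKM), Spry2, Rsrp1, Fzd7, Dstn, Zfp981, Utf1, Slc2a1 and Apex1. Rps20 and Rpl23 belong to a family with many processed copies, and they, Kpna1, Camk1d, Dstn, Zfp981 and Slc2a1 overlap other genes. At least 2-fold higher were 78 genes and lower 34, among 5240, but only 4 and 5 of these were protein-coding, and among genes listed in both files the counts were 40 and 5. The median shift of all genes was -0.11.

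In ATAC-seq the ESC groups overlapped, with 114635 ± 2404 intervals in KO and 112503 ± 6215 in WT (SD, n = 3; exact permutation p = 0.6), and the sign of this difference turned after thinning to the same background pileup (-539). Opened regions numbered 2410 and closed regions 2653, and 74602 regions were called in all 6 libraries. Gene ends opened at 45 protein-coding genes and closed at 36. The end of Mir17hg, a noncoding microRNA host gene of the lists and outside these counts, closed as well. The number opened minus closed was high among random lists for endoderm genes (4 opened, 0 closed, percentile 99.1).

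The fourth comparison was KO against WT in CM. Sarcomere, cardiac transcription factor, fibroblast and endoderm genes were lower and pluripotency genes were higher in CM KO. The sarcomere median was -1.06 (percentile 0), with all 6 genes in the filter lower, of which Ttn, Actc1, Myh6 and Myl7 passed the filter in CM WT alone. Over all 24 listed sarcomere genes the median was -0.16 (percentile 0), most of them at low RPKM. Titin (Ttn) stood at 0.140 against 2.18 RPKM (fold 0.0643, 0.0606 to 0.0682), Actc1 at 0.0962 against 1.90 RPKM (0.0507, 0.0285 to 0.0834), Myh6 at 0.0322 against 1.27 RPKM and the atrial light chain Myl7 at 0.0312 against 1.03 RPKM. The cardiac transcription factors had a median of -0.23 (percentile 0.01), with 7 of 9 lower and none by 2-fold on the log2(RPKM + 1) scale. Gata4 stood at 0.964 against 2.01 RPKM (fold 0.480, 0.456 to 0.506) and Hand2 at 0.929 against 1.76 RPKM, whereas Hand1 stood at 1.62 against 1.13 RPKM. Myh6 and Hand1 overlap other genes. Of 4 calcium and conduction genes (median 0.09, percentile 34.9), the sodium-calcium exchanger gene Slc8a1 stood at 0.233 against 1.86 RPKM and Gjc1 at 3.94 against 1.97 RPKM.

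Fibroblast and endoderm genes were lower. The fibroblast median was -1.10 (percentile 0), with 5 of 8 genes at least 2-fold lower, among them Col1a1 at 4.34 against 15.5 RPKM (fold 0.280, 0.267 to 0.294) and Lum at 0.340 against 2.54 RPKM, while Fn1 stood at 11.2 against 9.12 RPKM. With only genes of at least 5 RPKM in either library the fibroblast median was -0.16 (percentile 15.8). The endoderm median was -0.79 (percentile 0) with all 6 genes lower. Among them were Rbp4 at 1.20 against 4.49 RPKM and Afp at 0.135 against 1.00 RPKM. Fewer than 3 members of the list reached 1 RPKM in CM KO. Most of the 6 thus passed the filter through CM WT alone, which fixed their direction. Without the filter the medians were -0.20 for fibroblast and -0.19 for endoderm (percentile 0 for both), -0.12 for cardiac transcription factors (0) and 0.19 for pluripotency (99.99). Of smooth muscle genes, Acta2 stood at 1.00 against 2.53 RPKM. Of endothelial genes, Egfl7, which overlaps Mir126a, stood at 2.91 against 1.47 RPKM (1.98-fold, 1.78 to 2.21) and Flt1 at 1.06 against 0.939 RPKM, and of early mesoderm genes Kdr at 2.08 against 1.34 RPKM and Pdgfra at 0.730 against 1.23 RPKM. Flt1, Kdr and Pdgfra overlap other genes too. The pluripotency median was 0.42 (percentile 100), with 12 of 16 genes higher, led by Dppa5a at 3.24 against 1.27 RPKM (2.56-fold, 1.77 to 3.71) and Zfp42 at 2.02 against 0.837 RPKM (2.41-fold, 2.10 to 2.77), while Pou5f1 stood at 1.32 against 1.34 RPKM. Cell cycle genes were higher in 21 of 23 (median 0.25, percentile 99.3), with Mki67 at 9.35 against 5.13 RPKM. Immediate early genes were lower (median -0.10, percentile 0.46), with Zfp36 at 0.637 against 1.29 RPKM. Ribosomal proteins (0.31, 83.9), WNT and BMP genes (0.22, 90.5), cardiac energy metabolism (0.19, 74.7), the m6A machinery (0.18, 78.7), p53 targets (0.13, 38.7), chromatin regulators (0.10, 23.0) and chromatin-associated long noncoding RNAs (-0.06, 3.2) lay within the middle 95%, and with scaled libraries the medians of chromatin regulators and calcium genes turned to -0.05 and -0.06. The early mesoderm, smooth muscle, endothelial, blood, neural, interferon, skeletal muscle, 2-cell stage and mitochondrial lists had fewer than 3 members in the filter and no median.

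**Figure D2:**
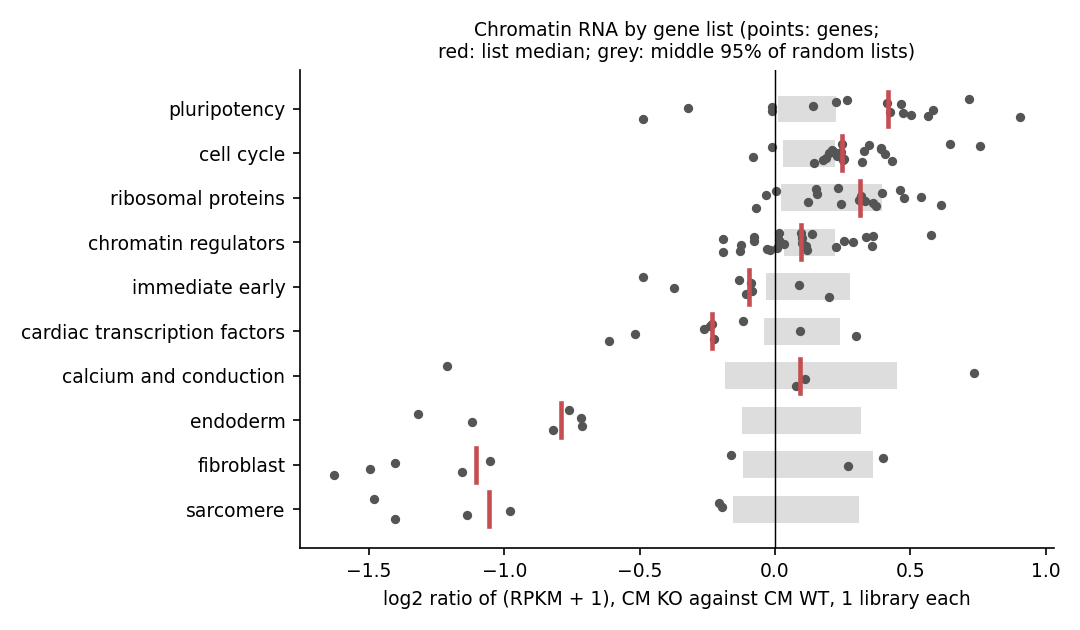
Log2 ratio of chromatin RNA (RPKM + 1) in CM KO against CM WT, 1 library each, for the genes of 10 lists. Points are genes, red bars list medians and grey boxes the middle 95% of the medians of matched random lists; sarcomere, fibroblast and endoderm medians lie to the left of their boxes (-1.06, -1.10 and -0.79) and the pluripotency median to the right (0.42).

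The highest single genes in CM KO against CM WT were Myo3a (9.09 against 2.24 RPKM, 4.06-fold), the metallothionein gene Mt2 (12.1 against 3.47 RPKM), the imprinted gene Peg10 (59.0 against 20.6 RPKM, 2.87-fold, 2.80 to 2.94), Hbb-bh1, Grcc10, Rps16, Ipo7, Bex1, Rpl37 and Hspa9. Among the 10 lowest, after Adnp, which was not listed in CM KO, were the imprinted gene Grb10 (0.380 against 7.05 RPKM, fold 0.0538, 0.0508 to 0.0571), Col1a1, Hbb-y, Apob, Thbs1, Lars2, Tmsb4x and Ccn2. Myo3a, Rps16, Ipo7, Bex1, Rpl37, Hspa9, Adnp, Grb10, Lars2 and Ccn2 overlap other genes. At least 2-fold higher were 109 genes and lower 71, among 5170, and 8 and 26 of these were protein-coding. The median shift was 0.18, and with scaled libraries the counts were 78 higher and 85 lower. The embryonic globins differed in direction, with Hbb-bh1 at 28.0 against 12.5 RPKM and Hbb-y at 5.94 against 18.2 RPKM.

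CM KO libraries had fewer ATAC intervals than CM WT libraries, 73177 ± 3128 against 88791 ± 5064 (SD, n = 3), a difference of -17.6% without overlap (exact permutation p = 0.1). The background pileup, a measure of depth, was also lower in CM KO, at 1.63 ± 0.0815 against 2.24 ± 0.258 reads per base, and after thinning to the same background pileup the difference was -10.3% and still without overlap. Closed regions numbered 7225 and opened regions 1458. The equal-number setting gave 4054 and 2632, and thinning to the same background pileup gave 5536 and 1915. On log2 interval numbers the KO effect was 0.03 in ESCs and -0.28 in CM, and their difference of -0.31 had p = 0.03 over 400 permutations of the genotype labels (-0.15 and p = 0.09 after thinning, -0.21 and p = 0.145 at a −log10 q of at least 5, and -0.27 and p = 0.055 without ESC WT replicate 3). This permutation takes no genotype effect in either cell type as its null.

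Regions that opened in WT differentiation were called less often in CM KO than in held-out CM WT libraries. A held-out CM WT library was called at 82.5 ± 8.15% (SD, n = 3) of the regions opened in the other WT libraries, and a CM KO library at 28.8 ± 1.72% (exact permutation p = 0.1, no overlap). Of regions closed in WT differentiation, 11.6 ± 1.59% were called in held-out CM WT libraries and 19.2 ± 3.87% in CM KO libraries (exact permutation p = 0.1, no overlap). Of all 11278 opened regions, 49.5% were called in no CM KO library and 17.6% in all 3. Of the 17 regions opened at sarcomere genes, 12 were called in no CM KO library, as were 14 of 22 at calcium and conduction genes and 9 of 24 at cardiac transcription factor genes, of which 8 were called in all 3. At Actc1 the region at chromosome 2 positions 114052723 to 114053113, at the gene end (gene 114047282 to 114052875), was called in 3 of 3 CM WT libraries and in no other library. At Gata4 (chromosome 14 positions 63198914 to 63271712) the regions 63247703 to 63248022, inside the gene, and 63271500 to 63271834, at its end, had the same pattern, and so did 81469048 to 81469322 on chromosome 17 inside Slc8a1.

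**Figure D3:**
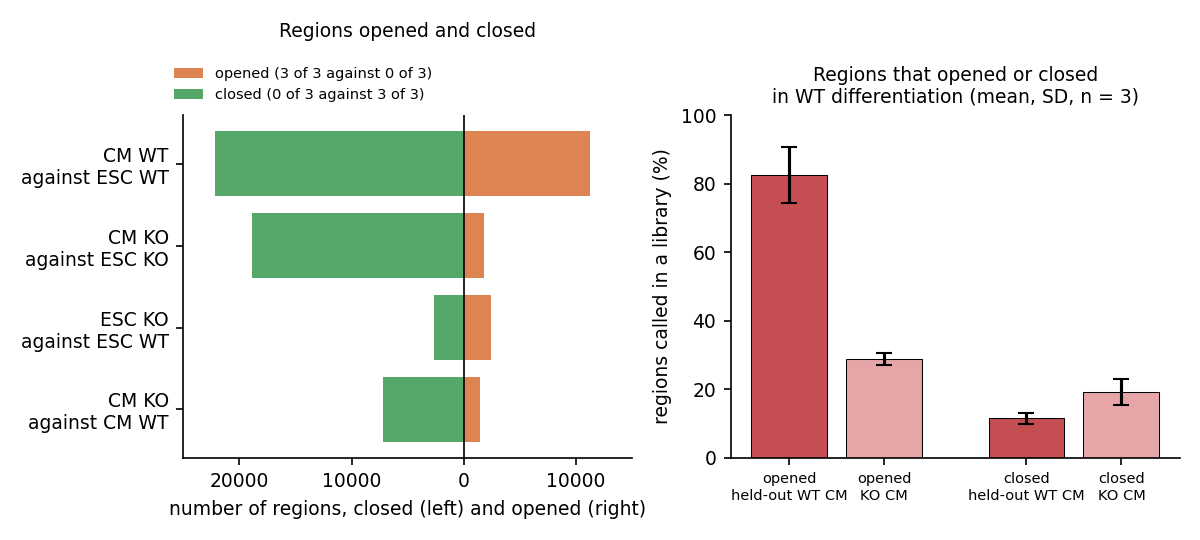
Left, number of union regions opened (right of 0) and closed (left of 0) in the 4 comparisons. Right, percent of regions opened or closed in WT differentiation that were called in held-out CM WT and in CM KO libraries, as mean and SD of 3 libraries; the opened regions were called at 82.5% in WT and 28.8% in KO.

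Gene ends closed in CM KO at 141 genes and opened at 29. Closed list members were Gata4, Actc1, the troponin gene Tnnt2, Ckmt2, Col3a1, Csf1r, Ttr and Ifit1, and opened ones Dppa3 and Elavl3, both of which had closed in WT differentiation. The end of the noncoding Meg3, outside these counts of protein-coding genes, closed as well. Of 108 protein-coding genes in the chromatin RNA table whose end closed, 16 had at least 1 RPKM in either library and a median log2 ratio of -0.24 at percentile 0, with 11 of 16 negative. Sarcomere genes with an interval at their end numbered 11.7 ± 0.577 of 28 in CM KO and 16 ± 2 in CM WT (SD, n = 3), and cardiac transcription factors 17.0 ± 1.00 and 19.3 ± 0.577 of 23. The exact permutation p was 0.1 for both and 0.48 after Benjamini-Hochberg adjustment over the lists. The pluripotency list had 28.7 ± 1.53 and 28.3 ± 1.15 of 33 (exact permutation p = 1). Among random lists, regions opened minus closed were low for fibroblast (0 opened, 11 closed, percentile 0.015), calcium and conduction (1 and 19, percentile 1.20) and sarcomere genes (1 and 13, percentile 2.06) and high for pluripotency genes (1 and 1, percentile 97.6).

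**Figure D4:**
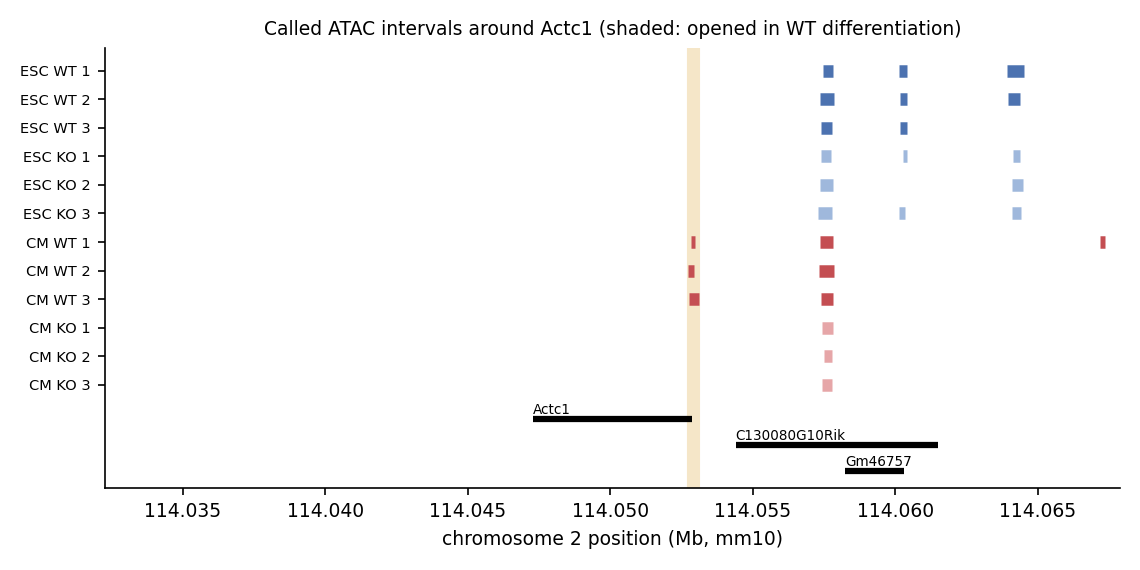
Called ATAC intervals (coloured bars) of the 12 libraries around Actc1 on chromosome 2 (mm10), with annotated genes as black bars. The shaded region at one end of Actc1 carries an interval in the 3 CM WT libraries and in no other library, while the interval to its right is called in all 12.

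The KO ratio of chromatin RNA was at least 2-fold higher in CM than in ESCs for 145 genes and lower for 144, among 6267. The list medians of this difference were -1.08 for sarcomere (percentile 0), -1.14 for fibroblast (0), -0.79 for endoderm (0.03), -0.15 for cardiac transcription factors (0.46), 0.36 for pluripotency (99.4), 0.37 for WNT and BMP genes (98.8) and 0.39 for cell cycle genes (99.6). No test of these differences is possible with 1 library each.

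Chrm6A-seq listed 16983 positions in 5367 genes in ESC WT and 18076 in 5342 genes in ESC KO, a ratio of 1.06. In CM it listed 25617 positions in 7572 genes in WT and 13962 in 4962 genes in KO, a ratio of 0.545. Within genes at 1 RPKM or more in both libraries the ratios were 1.11 and 0.620. Of the WT positions, 53.9% (53.2 to 54.7, Clopper-Pearson) were on the KO list in ESCs and 35.6% (35.0 to 36.2) in CM. Of the KO positions, 50.7% (49.9 to 51.4) were on the WT list in ESCs and 65.3% (64.5 to 66.1) in CM. The CM KO list was shorter than the CM WT list, which limits the share of WT positions found on it. CM WT had 1.51 times the positions of ESC WT, and 1.13 times within expressed genes. The motif GGAC made up 31.3% (30.6 to 32.0) of positions in ESC WT, 29.0% (28.3 to 29.7) in ESC KO, 33.5% (32.9 to 34.1) in CM WT and 32.8% (32.0 to 33.5) in CM KO. Mettl3 had no position in any list. With 1 list per group and unknown depth, these differences have no test of the condition.

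In CM every gene list with a position in WT had fewer positions in KO, as did the lists of all positions. Sarcomere genes had 180 positions in 9 genes in CM WT and 10 in 2 genes in CM KO. Most of these were in Ttn, with 151 positions in WT and 1 in KO at 2.18 and 0.140 RPKM, and without it the list had 29 and 9, of which Tpm1 held 22 and 9. The numbers of positions in WT and KO were for cardiac transcription factors 50 and 25, calcium and conduction genes 44 and 17, cardiac energy metabolism 18 and 3, endoderm genes 59 and 30 and interferon response genes 17 and 1. Interferon response genes with a position numbered 11 and 1. These lists include genes whose chromatin RNA was lower in CM KO, such as Actc1 (1 position and none, at 1.90 and 0.0962 RPKM). Positions were also on the WT and not the KO list for genes at similar RPKM, such as the corepressor gene Trim28 (3 and none, at 9.12 and 9.23 RPKM), Atp2a2, the sarcoplasmic calcium pump gene (2 and none, at 3.65 and 3.91 RPKM) and Smarca4 (2 and none, at 1.75 and 1.60 RPKM). Rplp0, Rps18, Dnmt3b, Apoa1 and Bax were also among the 10 highest expressed. Chromatin-associated long noncoding RNAs had 326 positions in WT and 245 in KO, of which 131 were on both lists, and pluripotency genes had 56 and 32 positions.

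In ESCs pluripotency genes had 131 positions in WT and 141 in KO, chromatin regulators 298 and 304, the m6A machinery 98 and 100, and chromatin-associated long noncoding RNAs 61 and 121. Kcnq1ot1 held 11 and 70 of the latter, and without it the list had 50 and 51. List members with a position in WT and none in KO had 1 position each and included Rps14, Bax, Hdac2, Ier3, Hdac3, Smtn, Kcnj3, Bbc3, Fos and Eng. The highest expressed genes on both lists were Gm42418, Gm22973, Gm26917 and Gm26316 in both cell types, with Gas5 in ESCs and Snhg1 in CM.

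**Figure D5:**
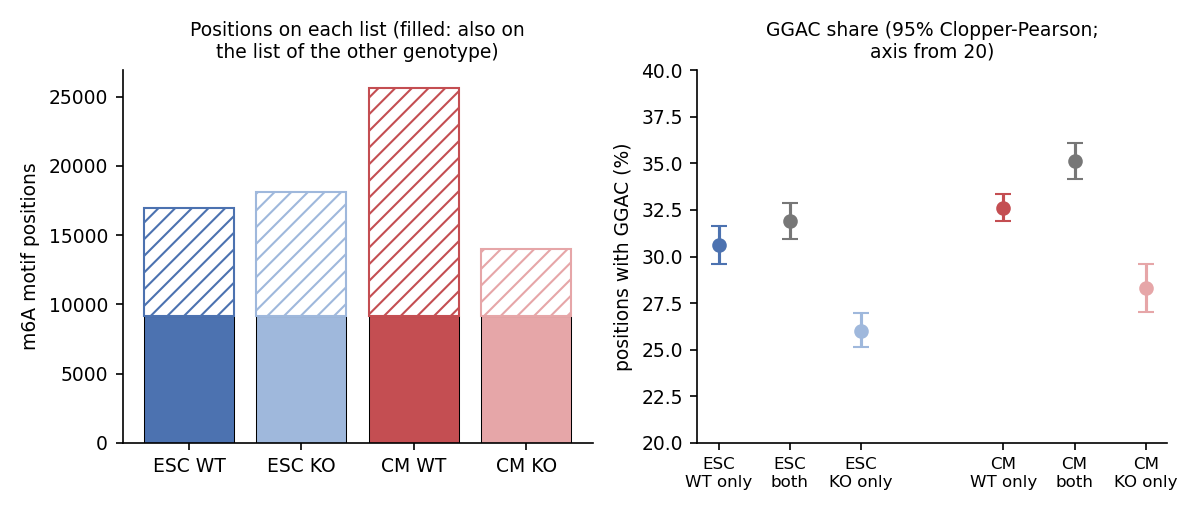
Left, number of m6A motif positions on each list, 1 list per condition; the filled part is also on the list of the other genotype of the same cell type. Right, percent of positions with GGAC among those on the WT list only, both lists or the KO list only, with 95% Clopper-Pearson intervals (axis from 20%); the KO-only positions have the lowest share, 26.0% in ESCs and 28.3% in CM.

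Chromatin RNA was compared between genes grouped by m6A status, among the genes with at least 1 RPKM in either library (5170 in CM, 5240 in ESCs). Of all genes on the m6A lists, 2725 held positions in CM WT alone, 115 in CM KO alone and 4847 in both, and in ESCs 696, 671 and 4671. In CM, the 892 genes with positions in WT and not in KO had a median log2 ratio of KO to WT of 0.07, below all matched random lists (random median 0.12, percentile 0), the 2945 with positions in both 0.13 (97.1) and the 1289 with none 0.14 (60.2). The 44 CM genes with positions in KO and not in WT had a median of 0.28 (random median 0.16, percentile 99.94), and the 273 with more positions in KO one of 0.22 (percentile 100). In ESCs the 265 genes with positions in WT and not in KO had a median of -0.16 (random median -0.10, percentile 0), the 3105 in both -0.10 (33.6), the 1550 with none -0.08 (93.7) and the 320 in KO and not in WT -0.06 (99.83). With genes of at least 5 RPKM the percentiles of the WT-only genes were 89.5 in CM and 52.7 in ESCs, within the middle 95% of random lists. A gene with less RNA also offers fewer reads for a position to be listed, and the assays do not separate these.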

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

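The tests chosen only after the result was seen were the thinning of libraries, the share of closed regions called in KO cardiomyocytes, the percentile of the pluripotency list, the GGAC share of KO-only positions, the interaction with each library left out and the other splits of the libraries.

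The KO effect on the log2 number of ATAC-seq intervals differed by -0.31 between CM and ESCs (permutation p = 0.03, with no KO effect in either cell type as the null), but p was 0.145 at a −log10 q of at least 5 and 0.055 without ESC WT replicate 3, so a difference between the cell types is not established. The tables argue against lower depth of the CM KO libraries, as far as the background pileup measures it, as the whole cause of their fewer intervals. After thinning to a common background pileup, 53.6% of the CM difference was left (50.1% to 59.3% with 1 library left out) and the highest CM KO library (76300 intervals) stayed below the lowest CM WT library (79524), although 46.4% was removed and the interaction was then -0.15 (permutation p = 0.09). Of regions closed in WT differentiation, the lowest thinned CM KO library was called at 18.8% and the highest held-out CM WT library at 12.1% (16.2% and 13.3% without thinning), values that cells with ESC-like chromatin in the KO cultures would give. Thinned ESC KO libraries had more intervals (110196 ± 1876, SD, n = 3) than thinned CM WT libraries (81002 ± 1809), but what a mixture of cell states does to the number of called intervals was not tested, so such cells and a direct effect of METTL3 loss stay open.

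The pluripotency list had a median log2 ratio of KO to WT of -0.15 in ESC and 0.42 in CM chromatin RNA, beside shifts of all genes of -0.11 and 0.18 (median difference per gene 0.36 against 0.23 for random lists, percentile 99.4), and it was not tested because each condition had 1 library. In the same CM comparison the sarcomere list had a median of -1.06 (-0.16 without the filter on low values), and scaling to a median ratio of 0 left it at -1.06. The shift of all genes went the other way, so scaling lowered CM KO values further. Most of these were already very low, where scaling hardly moves log2 of RPKM + 1. The median could hardly have moved, so this does not decide on normalization to abundant small RNAs. A lower share of heart muscle cells alone would raise the lists of the other cell types alike. The fibroblast list had a median of -1.10 at percentile 0 (-0.16 at percentile 15.8 with genes of at least 5 RPKM). The endoderm list had one of -0.79 at percentile 0, of smaller size without the filter on low values. Most endoderm genes in the filter passed it through CM WT alone, which fixed their direction. The remaining lists of other cell types had fewer than 3 expressed members and could not be scored. Their single genes went both ways, with endothelial Egfl7 at 2.91 against 1.47 RPKM and smooth muscle Acta2 at 1.00 against 2.53 RPKM. The medians thus speak for the fibroblast and endoderm lists only, and a lower share of heart muscle cells is not ruled out. The pluripotency median lay at percentile 100 and was smaller without the filter on low values. Of its genes, 12 were higher (among them Dppa5a, 3.24 against 1.27 RPKM, and Zfp42, 2.02 against 0.837 RPKM). The other 4 were lower (among them Dnmt3b, 1.87 against 3.02 RPKM). Cells that kept an ESC-like state in the KO culture could give a higher median. A direct effect of METTL3 loss on these genes and a difference between the single libraries stay open and were not tested.

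The number of m6A positions in KO relative to WT was 1.06 in ESCs and 0.545 in CM, a difference that was not tested because each condition had 1 list. In ESCs GGAC made up 26.0% (25.1 to 26.9) of KO-only positions and 30.6% (29.6 to 31.7) of WT-only positions. KO-only positions may thus come in part from enrichment that does not depend on the motif preference of METTL3. In CM, where the KO list was shorter, the shares were 28.3% (27.0 to 29.6) and 32.6% (31.9 to 33.3). The gap therefore does not tell why KO ESCs had as many positions as WT ESCs. Positions on both ESC lists held 31.9%. The GGAC share that such enrichment would give is not known, so these shares do not tell how much of the ESC KO list it covers. Genes of at least 1 RPKM with more positions in KO had a median log2 ratio of -0.049, above all matched random lists (median -0.09, percentile 100), a small difference in line with a contribution of expression. Residual METTL3 activity, another methyltransferase and the depth of these libraries stay open and were not tested.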

How the results depend on the processing

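The tests chosen only after the data were seen were thinning, gene body plus 2 kb, positions within 100 bases, genes listed in both files, the interaction with each library left out and the other splits of the libraries. Of 574 alternative values for 107 results, 466 were labelled unchanged, 96 moved, 3 kept their direction but lost the threshold and 9 were labelled reversed. The reversed values were 3 for ATAC-seq interval number and 6 for gene ends. Medians of chromatin RNA were not labelled reversed even where their sign turned, as for some lists with scaled libraries. For these medians the label unchanged does not show that sign or size was kept. Among the 574 values were 205 for list medians outside the main comparisons, of which 189 were labelled unchanged and 16 moved. Where no construction is named, the cause was not tested.

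The difference in interval number between ESC KO and ESC WT was -2619 at a −log10 q of at least 5, -539 after thinning and -557 to 5534 with 1 library left out, negative without ESC WT replicate 3. The ranges were -26625 to -20310 for CM WT against ESC WT, -43061 to -39936 for CM KO against ESC KO and -17288 to -12701 for CM KO against CM WT. The interaction was -0.21 at a −log10 q of at least 5 (permutation p = 0.145), -0.15 after thinning (p = 0.09) and -0.35 to -0.26 with 1 library left out; only without ESC WT replicate 3 did p pass 0.05 (-0.27, p = 0.055). Held-out differences ranged from -54.4 to -52.7 points for opened and from 5.45 to 9.14 for closed regions.

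At a −log10 q of at least 5 regions opened were 6709 for CM WT against ESC WT, 984 for CM KO against ESC KO and 1478 for ESC KO against ESC WT, and regions closed in CM KO against CM WT 4696. With an equal number of intervals, which drops the weakest of the larger libraries, opened regions were 3851 for CM KO against ESC KO, 1558 for ESC KO against ESC WT and 2632 for CM KO against CM WT, and closed regions 10244 for CM WT against ESC WT, 5102 for CM KO against ESC KO and 4054 for CM KO against CM WT. With 50% cover 1171 opened in CM KO against ESC KO. With calls in 2 of 3 libraries, a looser rule, opened and closed regions were 18729 and 35014 for CM WT against ESC WT, 3955 and 32435 for CM KO against ESC KO, 7584 and 7122 for ESC KO against ESC WT and 4509 and 15658 for CM KO against CM WT. With 1 library left out they ranged over 11692 to 14988 and 24598 to 28293, 2045 to 2606 and 21279 to 24228, 3148 to 4400 and 3519 to 4800, and 1950 to 2796 and 8605 to 11224, in the same order. The count passed 1.5 times the main one in ESC KO against ESC WT for opened regions without ESC KO replicate 1 (4078), 2 (4400) or 3 (3926) or ESC WT replicate 1 (4071), and for closed regions without ESC WT replicate 2 (4109) or 3 (4800). In CM KO against CM WT it did so for opened regions without CM KO replicate 1 (2796) or 3 (2559) or CM WT replicate 2 (2210), and for closed regions without CM WT replicate 3 (11224). Fewer libraries must meet the rule then, so counts rise by construction.

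With the replicate block, a looser rule on same-numbered pairs, opened and closed regions were 20452 and 43729 for CM WT against ESC WT, 4723 and 42601 for CM KO against ESC KO, 11005 and 10484 for ESC KO against ESC WT and 6417 and 20303 for CM KO against CM WT. Deviations of same-numbered libraries correlated between -0.0096 and 0.0050, so pairing by number is not shown, and such values do not exclude it. Every library correlated best with its own number only in ESC KO against ESC WT. Exact paired sign-flip tests cannot go below p = 0.25.

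With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; 1 of the 10, the real one, gave as many changed regions as the real one in each comparison. The real split gave 33433, 20677, 5063 and 8683 regions for CM WT against ESC WT, CM KO against ESC KO, ESC KO against ESC WT and CM KO against CM WT, and the highest other split gave 512, 591, 978 and 771.

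Differences in genes with an interval at their end changed as follows. Pluripotency, CM WT against ESC WT (-1.67), was 1 at 2 kb and 0 over the gene body, and -2 to -1 with 1 library left out. Pluripotency, CM KO against CM WT (0.333), was -0.667 at 2 kb, -0.333 over the gene body and -0.333 to 1.17 with 1 library left out, negative without CM KO replicate 2 or CM WT replicate 1. Cardiac transcription factors, CM WT against ESC WT, were 0 at 500 bp and over the gene body and 0.833 to 1.83 with 1 library left out; in CM KO against CM WT they were 0 over the gene body and -2.83 to -1.83. Sarcomere genes, CM WT against ESC WT, were 0 at 2 kb, over the gene body and after thinning and 0 to 2 with 1 library left out, with 0 without CM WT replicate 2; in CM KO against CM WT the range was -5.33 to -3.33. Calcium genes, CM WT against ESC WT, were 0 at 500 bp and 0.333 to 0.833; in CM KO against CM WT they were 0.333 with an equal number of intervals and -1.83 to -1.33.

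Counts of genes at least 2-fold higher or lower moved with the pseudocount and filter by construction. With a pseudocount of 0.1, 94 were lower in ESC KO, 168 higher in CM KO against CM WT, 552 higher and 1002 lower in CM WT against ESC WT, 585 and 386 in CM KO against ESC KO, and 378 had a higher KO ratio in CM. At 5 RPKM the higher and lower counts were 36 and 15, 63 and 31, 80 and 169, and 92 and 94 for ESC KO against WT, CM KO against WT, CM WT against ESC WT and CM KO against ESC KO, and 78 and 81 for the KO ratio in CM. Genes listed in both files gave 40 and 5 in ESCs and 72 and 43 in CM. Scaling to a median ratio of 0 gave 459 and 249 in CM WT against ESC WT.

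The share of m6A positions found again was 71.6% in ESCs, 46.4% in CM, 70.7% for ESC WT positions in CM WT and 51.0% for ESC KO positions in CM KO within 100 bases, a looser rule, and 55.3%, 39.9% and 37.3% in expressed genes for ESCs, CM and ESC KO positions in CM KO. At 5 RPKM the median log2 ratio of KO to WT was 0.0025 for WT-only genes, -0.10 for genes with positions in both and 0.20 for genes with none in ESCs, and 0.36 for WT-only genes in CM.

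Not run were the strict part of each m6A list by score and 50% overlap of m6A peaks, since the lists hold no score or width, the join to m6A at 50% overlap and the motif share against flanking sequence for the same reason and for want of a genome, and replicate fits of chromatin RNA, since each condition has 1 file. Depth limits the ATAC-seq lists, where a region not called is not shown to be closed.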

Other observations

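The tests of overlap given here were chosen only after the values were seen, and the genes were named after their values were seen.

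Genes at least 2-fold higher in KO in both cell types numbered 8 (1.36 expected of independent lists). Genes lower in both numbered 9 (0.385 expected). Most of the higher genes were not listed in either WT file, and most of the lower genes were not listed in ESC KO. They were taken as 0 there, and absence can also come from reads assigned to an overlapping gene. The ESC and CM comparisons share no library, but the CM cultures were derived from the ESCs. A difference between the WT and KO lines that is unrelated to METTL3 could thus appear in both, and this was not tested. The protein-coding ones were Grcc10, higher at 146 against 61.6 RPKM in ESCs and 80.4 against 37.6 RPKM in CM, and Grb10, Armcx5 and Cntf, lower. Grb10, an imprinted gene that encodes a growth factor receptor adaptor and overlaps LOC102631979, stood at 0.194 against 3.55 RPKM in ESCs and 0.380 against 7.05 RPKM in CM. Armcx5 (1.10 and 1.07 RPKM in the WT libraries) and Cntf (1.41 and 1.10 RPKM) were not listed in either KO file, and both overlap other genes. The others were mostly small RNAs, among them Mir302c and Mir367, which overlap Larp7 and were lower.

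Kcnq1ot1, an imprinted long noncoding RNA that overlaps Kcnq1, held 11 m6A positions in ESC WT, 70 in ESC KO, 51 in CM WT and 77 in CM KO, of which 8 were shared between the ESC lists and 28 between the CM lists. Its chromatin RNA was 2.19-fold (2.14 to 2.25) higher in KO in ESCs and 2.26-fold (2.21 to 2.31) in CM, with intervals that cover counting error only.

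Xist, which coats the inactive X chromosome and overlaps Tsix, stood at 0.0203, 0.0265, 0.0521 and 0.760 RPKM in ESC WT, ESC KO, CM WT and CM KO, or 13, 17, 35 and 518 estimated reads. All 12 ATAC-seq libraries held intervals on chromosome Y, between 19 and 41.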
